A study of Mus musculus with 30 samples.

How the data were processed

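The series measured transcripts of peripheral blood mononuclear cells (PBMC), the lymphocytes and monocytes of blood, from female C57BL/6 mice aged 6 weeks. Per the labels' protocols, mice received oleic acid (OA), a fatty acid that injures the lung when injected into a vein, at 1.2 µl/g, or physiological serum, both as 200 µl into the tail vein. Blood of 200 to 900 µl per animal was layered on Ficoll of density 1.084 g/ml, and 200 ng of total RNA was labelled with Cy3 in 1 colour. The design text counts 30 mice and there are 30 arrays, so each array was taken as 1 animal. Serum groups held 3, 3, 2, 1, 2 and 2 arrays and OA groups 3, 3, 3, 2, 3 and 3 arrays at 1, 1.5, 3, 4, 18 and 24 h. Replicate numbers only name an array within its group.

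Per the file headers, the arrays were Agilent mouse expression arrays with 62976 spots, read with Feature Extraction 10.5.1.1, and the deposited scanner intensity values are linear signals before normalization between arrays. The processed signal used here is corrected for background within each array, per the file headers. A deposited table of the authors' processed values, which lie on a log2 scale by comparison with the scanner intensity values, was used only as an alternative. Its 62927 rows had column medians of 5.35 to 5.36, and all 30 columns matched their own array best. Deviations from the row mean followed normexp-corrected signals (median correlation 0.977) and mean signals (0.968) more closely than processed signals (0.841). Its background correction, scaling and centring are not given in the sources used here.

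Of the spots, 3671 were controls and 59305 were not. Control spots and spots with Agilent's outlier mark (91 to 1408 per array, median 182) were left out, and no spot was saturated. The base-2 logarithm of the processed signal was taken, and each array's 75th percentile over all non-control probes was subtracted, so values are log2 levels relative to that percentile. Spots of 1 probe were averaged, although 55249 of 55681 probes had a single spot. A probe was kept where it was well above background on at least 3 of the 30 arrays, which left 35895 probes. Of several kept probes of a gene the one with the highest mean was used (7013 genes), giving 25206 genes or unnamed transcripts, 15012 of them with a symbol. Names came from the reference tables of the GRCm38.p6 assembly by accession (26762 probes), by symbol (3819) or by an older symbol (639). The other 24461 probes kept the file's name. Probe coordinates are those of the files, in mm9.

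A probe that was not well above background on any array of a group has only a bound there. Its fold is then printed as "at least", the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own.

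A linear model with 12 groups, 1 for each treatment and time, was fitted to all arrays with limma 3.58.1 in R 4.3.3, with 18 residual degrees of freedom and empirical Bayes moderation (prior degrees of freedom 3.97, median residual SD 0.599). Contrasts were OA minus serum at each time, the mean of the 6 differences, and the mean difference at 18 and 24 h minus that at the 4 earlier times. F tests asked whether the OA effect differed between times and whether the serum groups, or the OA groups, differed between times. The 4 h serum group has 1 array, which is assumed to vary like the other groups. Adjusted p values are Benjamini-Hochberg values over all genes of a contrast, with a threshold of 0.05, and all tests were two-sided. The 24 h comparison shares its arrays with the mean, the late minus early contrast and the F tests, so these are not independent.

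Gene lists for 23 cell types and pathways, with 312 members of which 287 were measured, were fixed before the data were examined. They cover neutrophils, immature neutrophil granule genes, monocytes, dendritic cells, B cells, T cells, natural killer (NK) cells, platelets, erythroid cells, and lung epithelium and endothelium. Pathway lists cover immediate early genes, inflammatory cytokines and NF-kB targets, interferon-stimulated genes, glucocorticoid-responsive genes, anti-inflammatory genes, hypoxia and glycolysis, PPAR targets and fatty acid oxidation, NRF2 targets, the unfolded protein response, heat shock, adhesion and chemotaxis receptors, cell cycle and circadian clock genes. Each list was tested against all other genes with limma's camera at the preset correlation of 0.01. Adjustment ran over the 184 tests of 23 lists and 8 contrasts. The same tests were run with a correlation estimated for each list, and with fry, which asks whether a list's genes move on balance in 1 direction without comparing them with other genes. For list tests 1051 missing values were filled with group means, and 15 genes with a group without any value were left out. Members were also adjusted over the list alone.

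The named genes followed a rule also fixed before the data were examined. At each time the 6 largest rises and 6 largest falls past the threshold with a gene symbol and without overlap between OA and serum were taken (10 and 10 for the mean, without the overlap condition), with up to 3 members of each list of smallest p. Where fewer than 5 genes passed, the 5 of smallest p were taken, and for late minus early and each F test the 8 of smallest p with a symbol. That the 5 of smallest p should have a symbol was added after the data were seen. List members that did not pass are given as values. Some genes that the rule takes are not reported here.

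Alternatives were quantile normalization, scaling to the median of probes above background on all arrays, normexp correction of mean and background signals with an offset of 50, no filter, a filter at 15 arrays and the mean of a gene's probes. Further alternatives were slide as a fixed or random block, scan day as a block, the replicate number as a block, array weights, a mean-variance trend with robust moderation, the deposited value table, leaving out each array in turn, only the 2 groups of a time, and the mean without the 4 h groups. Chosen after the data were seen were fits without the 3 arrays of low correlation, the intergenic signal of each array as a covariate, late minus early without the 4 h groups, and permutation of list scores. The intergenic signal is the median of 8630 kept long intergenic RNA probes minus the median of 14590 probes above background on all arrays, on the log2 scale. List scores, the per-array mean over a list's genes, were scaled to the median of probes above background on all arrays and compared by permuting treatment within time, exactly where possible and otherwise with 100000 draws.

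Gene and list tests were tested on simulated data with the real arrays' means and spread for 25206 genes. At a shift of 2 on the log2 scale, 47%, 54%, 38%, 4%, 42% and 39% of changed genes were called at 1, 1.5, 3, 4, 18 and 24 h, and 97% for the mean of the times. At a shift of 1 these shares were 3%, 1%, 1%, 0%, 0% and 2%, and 58% for the mean. Among genes left unchanged, 2, 3, 0, 1, 4 and 5 were called at these times and 13 for the mean. Each of the 23 lists was raised in turn at 1.5 h. A shift of 1 was called for 21 lists and a shift of 2 for 23, with 0 other lists called. Simulated genes were drawn independently of each other, without slide effects or outlying arrays. These draws therefore cannot show how the list tests behave where the genes of a list vary together. An earlier form of this list test, with 1 list and 1 draw, had missed a shift of 1 by a small margin and was replaced by this wider one. Python 3.11.15, numpy 2.4.6, matplotlib 3.10.9 and the R package data.table (version 1.17.8) were used to make tables and plots. Per-read depth does not apply to arrays, and their number limits the precision.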

Results

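Transcripts of peripheral blood mononuclear cells were measured on 30 arrays, 1 per mouse, after injection of oleic acid (OA, 17 arrays) or physiological serum (13 arrays). Serum and OA groups held 3 and 3 arrays at 1 h, 3 and 3 at 1.5 h, 2 and 3 at 3 h, 1 and 2 at 4 h, 2 and 3 at 18 h, and 2 and 3 at 24 h. The 75th percentile of the processed signal ranged from 40.2 to 152 between arrays, and 35.4% to 65.1% of probes were well above background. The number of arrays limits the precision, above all at 4 h with its single serum array. Differences are log2 values of OA minus serum with limma's standard error (SE), which rests on all 12 groups.

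Arrays differed in ways that treatment and time do not set. They came from 5 slides and 2 scan days, and slide 5 held 5 OA arrays only. These 5 arrays alone made up 1 of the scan days, so that day cannot be told apart from slide 5. Pairwise correlations ran from 0.739 to 0.984, and 3 arrays had a median correlation below 0.9: serum 24 h replicate 1 (0.813), OA 4 h replicate 2 (0.850) and serum 1.5 h replicate 3 (0.895). These arrays also had high signal from long intergenic RNA probes relative to probes always above background, at −1.96, −2.17 and −3.23. By group, the intergenic signal averaged −2.90 (SD 1.33, n = 2) in serum and −4.69 (SD 0.101, n = 3) in OA at 24 h, and was −4.32 in the serum array and −2.92 (SD 1.07, n = 2) in OA at 4 h. At 1 h it was −3.92 (SD 0.484) in serum and −4.65 (SD 0.449) in OA, at 1.5 h −3.78 (SD 0.541) and −4.52 (SD 0.346), at 3 h −4.03 (SD 0.558) and −4.40 (SD 0.509), and at 18 h −4.37 (SD 0.635) and −4.37 (SD 0.360). Across the 6 times treatment made no detectable difference to it (permutation p = 0.271). Whether it comes from genomic DNA or from the state of the RNA is not given in the sources used here. Transcripts of cells other than lymphocytes and monocytes also varied. Per array the neutrophil list averaged 2.33 to 5.66 and the erythroid list 4.32 to 6.84. The list tests cannot tell a change in that mix of cells from a response of the cells.

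**Figure D1:**
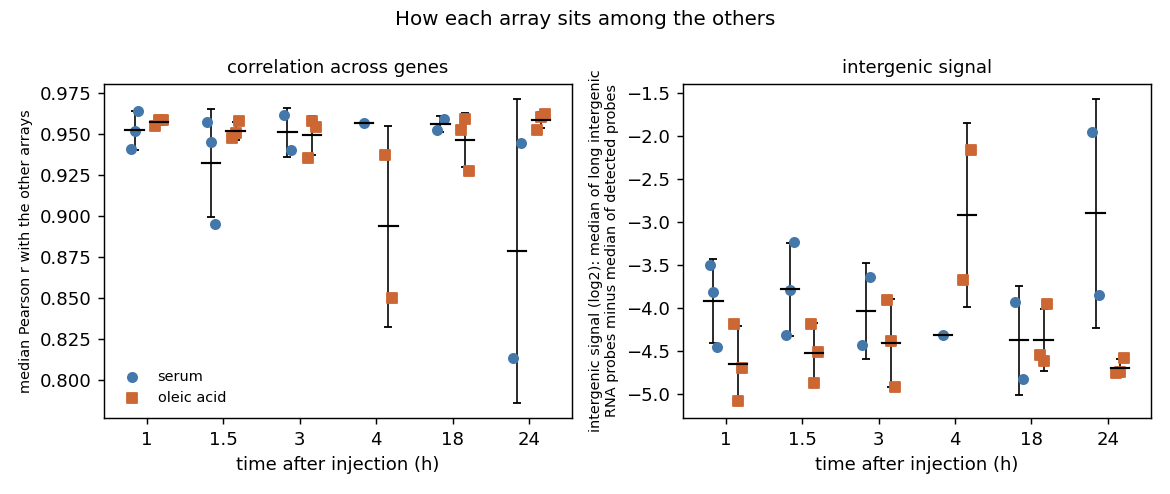
Median Pearson correlation of each array with the other arrays (left) and its intergenic signal on the log2 scale (right) by hours after injection, with serum arrays as blue circles, OA arrays as orange squares, group means as black lines and SD as bars. Serum 24 h replicate 1 lies at 0.813 and −1.96, and OA 4 h replicate 2 at 0.850 and −2.17.

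The choice of scaling moved the median of all genes by more than 0.1 in each comparison but that at 18 h. With the median of always-detected probes in place of the 75th percentile, that median went from −0.05 to −0.20 at 1 h, from 0.09 to −0.16 at 1.5 h, from 0.13 to −0.04 at 3 h, and from −0.17 to 0.39 at 4 h. It also went from 0.05 to −0.55 at 24 h, from −0.02 to −0.12 for the mean of the times and from 0.10 to −0.19 for late minus early. With quantile normalization it went to 0.17 at 24 h, and with normexp correction to −0.06 at 1.5 h, −0.07 at 3 h, −0.02 at 4 h and −0.15 at 24 h. List tests compare a list with all other genes, so they are relative to this shift.

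The 1 h groups asked how blood cell transcripts stood soon after the injection. Immediate early genes, which cells switch on within minutes of stimulation, rose as a list after OA (mean 0.79, 14 of 15 members above 0, camera adjusted p = 5.65e-05, and adjusted p = 0.754 with an estimated correlation). Among them Fos differed by 1.51 (SE 0.67) and Atf3, a stress-induced transcription factor, by 0.99 (SE 0.47), with 3 arrays per group, while Egr2 was not well above background in serum. Neutrophil markers rose as a list (mean 0.78, 13 of 14 above 0, adjusted p = 0.00163, and adjusted p = 0.754 with an estimated correlation), with Slpi at 1.41 (SE 0.75) and Clec4d at 1.31 (SE 0.72), while Csf3r, the receptor for granulocyte colony-stimulating factor, stood at −0.77 (SE 0.35). B cell markers also rose (mean 0.54, 12 of 13 above 0, adjusted p = 0.000439), with Blnk at 0.89 and Fcrla at 0.81. For this list adjusted p = 0.754 with an estimated correlation.

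Smaller shifts at 1 h concerned 5 further lists. The unfolded protein response (mean 0.40, adjusted p = 0.0139, Hspa5 0.66), glucocorticoid-responsive genes (0.40, 0.0188, Cebpd 1.17), platelet markers (0.45, 0.0298), NRF2 targets (0.48, 0.0393, Nqo1 1.72 with SE 0.82) and hypoxia and glycolysis genes (0.31, 0.0394, Vegfa 1.16, P4ha1 −0.88) rose as lists. None of these calls held with an estimated correlation (adjusted p = 0.754 with an estimated correlation as the lowest at this time). No single gene passed at 1 h in limma (0 genes, 1287 at an unadjusted p under 0.05), nor any list member adjusted over the list alone. The smallest p values with a symbol belonged to Mcm8 (−2.59, SE 0.58, at least 2.19-fold lower where it was not well above background), Rep15 (−2.11, SE 0.49), Tmem253 (−1.78, SE 0.43), Spata32 (−1.34) and Dstyk (1.53, SE 0.38, at least 1.06-fold), all at adjusted p = 0.824. OA and serum did not overlap for 11.5% of genes, where chance gives 10%. With slide as a block the immediate early (0.61, adjusted p = 0.00274), neutrophil (1.05, 2.31e-05) and B cell (0.0219) calls held, while the unfolded protein (0.227), glucocorticoid (0.794), platelet (0.283) and hypoxia (0.312) calls did not. Within slide 1 the differences were −0.04 for immediate early genes, 0.54 for neutrophil, 0.26 for B cell, 0.15 for platelet and 0.82 for NRF2 genes, 0.05 for glucocorticoid-responsive, 0.00 for hypoxia and −0.09 for unfolded protein genes. Leaving out serum 1 h replicate 1 ended the neutrophil (adjusted p = 0.0745), glucocorticoid (0.102), hypoxia (0.33), unfolded protein (0.137) and NRF2 (0.0622) calls. OA 1 h replicate 2 did so for platelet (−0.01, 0.696), glucocorticoid (0.0554), hypoxia (0.145) and unfolded protein (0.0505) genes. So did serum 1 h replicate 3 for platelet (0.201) and NRF2 (0.133), serum 1 h replicate 2 for hypoxia (0.136), OA 1 h replicate 1 for NRF2 (0.128) and OA 1 h replicate 3 for glucocorticoid genes (0.0669). Over the alternatives adjusted p for these 8 lists ran from 2.70e-07 to 0.971. The intergenic signal, lower after OA at 1 h, moved with these lists, and with it as a covariate the immediate early (0.38, 0.00917) and neutrophil (0.00812) calls held and the B cell call did not (0.234), while platelet (−0.31) and hypoxia genes (−0.04) turned direction.

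At 1.5 h the most marked group was platelet markers. All 13 measured members had higher means after OA, and the list rose by 1.91 (camera adjusted p = 2.36e-10, and adjusted p = 0.754 with an estimated correlation). Pf4, a chemokine of platelet granules, differed by 1.81 (SE 0.61), Ppbp by 1.72 (SE 0.62), Itgb3, the fibrinogen receptor subunit, by 2.01 (SE 0.58) and Gp1ba by 2.04 (SE 0.63). No member passed over all genes, but 13 of 13 passed adjusted over the list alone. Pf4 and Ppbp are neighbours on chromosome 5, with probes at 91202275 to 91202334 and 91198970 to 91199029 (mm9). For permutation, list scores were scaled to the median of probes above background on all arrays. An exact permutation of the platelet score at 1.5 h alone (difference 1.65) gave p = 0.1, the smallest that 3 against 3 arrays allow. B cell, erythroid, dendritic cell and cell cycle genes also reached this p at 1.5 h, though the dendritic cell and cell cycle lists were not called. The permutation p was 0.2 for immediate early, 0.3 for hypoxia, 0.4 for inflammatory and 0.9 for interferon-stimulated genes. Over the 4 early times together exact permutation gave p = 0.0143 for platelet genes (difference 0.73), adjusted 0.127, and 0 of 23 lists passed, with 6 at an unadjusted p under 0.05. The mean of the platelet list per array was 4.12 (SD 0.714, n = 3) in serum and 6.03 (SD 0.955, n = 3) in OA.

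**Figure D2:**
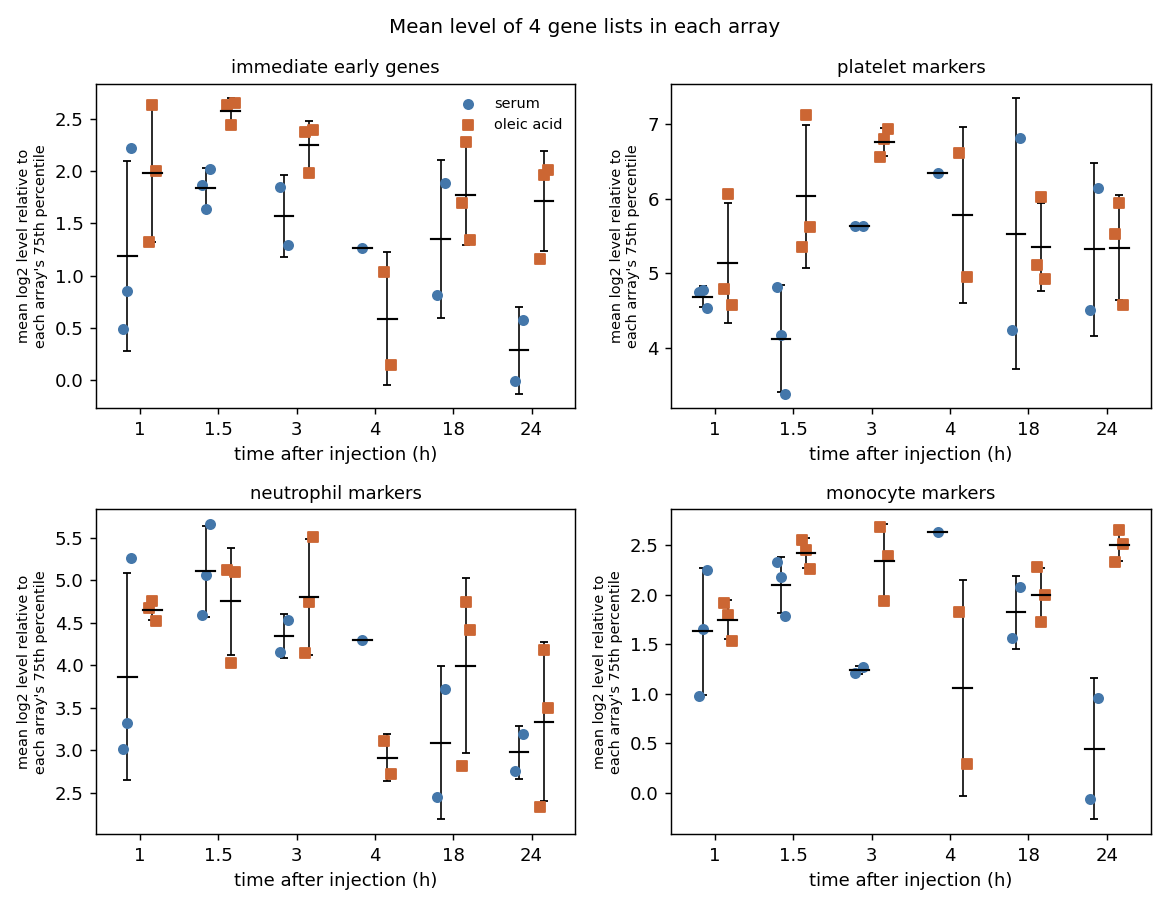
Mean log2 level, relative to the 75th percentile of the array, of immediate early, platelet, neutrophil and monocyte genes by hours after injection, with serum arrays as blue circles, OA arrays as orange squares, group means as black lines and SD as bars. Platelet genes averaged 4.12 in serum and 6.03 in OA at 1.5 h, and monocyte genes 0.45 and 2.5 at 24 h.

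Inflammatory cytokine and NF-kB target genes rose as a list at 1.5 h (mean 0.70, 12 of 15 above 0, adjusted p = 0.0103, and adjusted p = 0.754 with an estimated correlation). Ccl2, a chemokine that draws monocytes, differed by 1.77 (SE 0.48, list p 0.0187) and Tnfaip3, an inhibitor of NF-kB signalling, by 1.58 (SE 0.49, 0.0285), and both passed adjusted over the list alone, with 0 over all genes. Immediate early genes rose (mean 0.73, 14 of 15 above 0, adjusted p = 0.00433, and adjusted p = 0.754 with an estimated correlation). Atf3 differed by 1.94 (SE 0.47), from 0.09 (SD 0.441, n = 3) in serum to 2.03 (SD 0.213, n = 3) in OA, and was the 1 member to pass adjusted over the list alone (0.0067). B cell markers (mean 0.66, 13 of 13 above 0, adjusted p = 0.00142, Cd79a 0.86), hypoxia genes (0.51, 15 of 15, 0.0155, Ndrg1 1.49) and interferon-stimulated genes (0.38, 13 of 17, 0.0312, Cxcl10 1.48 with SE 0.59) rose as lists, each at adjusted p = 0.754 with an estimated correlation. Erythroid markers fell as a list (mean −0.70, 14 of 16 below 0, adjusted p = 0.0122), with Alas2, the first enzyme of heme synthesis in red cells, at −1.69 (SE 0.61), while Gata1, shared with megakaryocytes, stood at 1.59 (SE 0.53). For all 6 of these lists the call ended with an estimated correlation (adjusted p = 0.754 with an estimated correlation). Adjusted over the list alone, Vwf of the lung list, which megakaryocytes also make, differed by 2.02 (SE 0.63), and Hmox1 by −1.38 and Srxn1 by 1.91 among NRF2 targets, although those lists were not called.

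No single gene passed at 1.5 h in limma (0 genes, 2547 at an unadjusted p under 0.05). Among genes with a symbol the smallest p values belonged to Nmral1 (1.5, SE 0.33), Gpm6b (2.62, SE 0.62), Atf3, Mtss2 (2.72, SE 0.67, at least 5.73-fold) and Triqk (2.78, SE 0.69, at least 2.13-fold), at adjusted p = 0.47, Mtss2 and Triqk being not well above background in serum. Groups did not overlap for 25.5% of genes, against 10% by chance. With slide as a block the platelet call held (2.18, adjusted p = 4.97e-08), as did inflammatory (0.87, 0.00397), immediate early (0.97, 0.00113), B cell (0.96, 3.88e-05), erythroid (−0.73, 0.0465) and hypoxia (0.0167) calls, but not the interferon call (0.0901). Within slides 3 and 4 the platelet difference was 2.95 and 2.23, the immediate early 0.80 and 0.64 and the inflammatory 0.69 and 0.42. Those of the other lists were, for B cell genes, 0.71 and 1.19, for erythroid −0.80 and −0.45, for hypoxia 0.54 and 0.46 and for interferon genes 0.88 and 0.10. Without 1 array the inflammatory (0.051, serum 1.5 h replicate 2), erythroid (0.102, serum 1.5 h replicate 1) and interferon calls (0.526, OA 1.5 h replicate 2, and 0.0796, serum 1.5 h replicate 1) ended, and adjusted p over the alternatives of these 7 lists ran from 1.49e-15 to 0.754. The intergenic signal was lower after OA here too, and with it as a covariate the platelet difference was 1.14 (adjusted p = 2.05e-13) while the B cell (0.0676), immediate early (0.11), hypoxia (0.407) and erythroid (0.0771) calls ended.

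At 3 h monocyte markers rose as a list after OA, with all 13 members above 0 (mean 1.1, camera adjusted p = 0.000109, and adjusted p = 0.754 with an estimated correlation). The list averaged 1.24 (SD 0.0397, n = 2) in serum and 2.34 (SD 0.375, n = 3) in OA. Over all genes 0 members passed, and 1 passed adjusted over the list alone. Cd300e differed by 1.96 (SE 0.68) and F13a1, a coagulation factor subunit, by 1.61 (SE 0.60). Platelet markers again rose as a list (mean 1.13, 13 of 13 above 0, adjusted p = 0.000617, and adjusted p = 0.754 with an estimated correlation), with Ppbp at 1.64 (SE 0.70), Pf4 at 1.46 (SE 0.69) and Gp6 at 1.46. The platelet list averaged 5.64 (SD 0.000512, n = 2) in serum and 6.77 (SD 0.187, n = 3) in OA.

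Hypoxia and glycolysis genes (mean 0.70, 15 of 15 above 0, adjusted p = 0.00149, Hk2 1.46, at least 1.16-fold and not well above background in serum), glucocorticoid-responsive genes (0.70, 11 of 11, 0.00663, Zbtb16 0.93) and the unfolded protein response (0.64, 10 of 10, 0.015, Atf4 1.04) rose as lists at 3 h, each at adjusted p = 0.754 with an estimated correlation. Inflammatory (0.73, 13 of 15, 0.0318), interferon-stimulated (0.57, 14 of 17, 0.0332) and immediate early genes (0.68, 10 of 15, 0.0412, Nr4a1 1.75 with SE 0.61) did so too. None of these 6 calls held with an estimated correlation (adjusted p = 0.754 with an estimated correlation as the lowest at this time). Cxcl10, an interferon-induced chemokine, differed by 2.67 (SE 0.65, at least 1.93-fold) and passed adjusted over the list alone (0.00861), but its probes disagreed, from −0.06 to 2.67. Lung markers were not called (mean −0.45, adjusted p = 0.12), though Scgb1a1 at −1.94 (SE 0.73) passed adjusted over the list alone (0.0421), and Sftpc was not well above background in either group.

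No single gene passed at 3 h in limma (0 genes, 1956 at an unadjusted p under 0.05). Smallest among genes with a symbol were the p values of Naip6 (2.28, SE 0.47, at least 2.62-fold, adjusted p = 0.382), Asph (2.29, SE 0.47, at least 2.64-fold, its probes from −0.03 to 2.29), Cpeb2 (2.71, SE 0.57, at least 1.83-fold, 0.398), Plagl1 (−1.82, SE 0.39, 0.412) and Leo1 (1.79, SE 0.39, 0.419). Groups did not overlap for 30.6% of genes, against 20% by chance. With slide as a block the monocyte (1.14, adjusted p = 0.000254), platelet (1.33, 0.000254) and hypoxia (0.83, 0.000441) calls held, and of the 8 calls only the interferon call did not (0.089). Within slide 1 the differences were 0.67 for monocyte, 1.17 for platelet, 0.57 for hypoxia, 0.78 for glucocorticoid-responsive, 0.65 for unfolded protein, 0.37 for inflammatory, 0.57 for interferon and 0.69 for immediate early genes. Leaving out OA 3 h replicate 3 ended the inflammatory (0.117), immediate early (0.118), interferon (0.302), glucocorticoid (0.203) and unfolded protein (0.113) calls, leaving out serum 3 h replicate 2 ended the immediate early (0.35) and unfolded protein (0.232) calls. Serum 3 h replicate 1 did so for the inflammatory (0.0869) and interferon (0.107) calls. The inflammatory (0.0577) and immediate early (0.062) calls also ended without OA 3 h replicate 1, the interferon call without OA 3 h replicate 2 (0.0674), the immediate early call without either serum 24 h array (0.0607 and 0.0616). Across alternatives adjusted p ran from 1.31e-06 to 0.759. With the intergenic signal, slightly lower after OA, as a covariate the monocyte (0.00234) and platelet (0.74, 0.0073) calls held, and the inflammatory (0.104), interferon (0.18) and immediate early (0.286) calls ended.

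The 4 h comparison set 2 OA arrays against a single serum array. Monocyte markers fell as a list (mean −1.58, 13 of 13 below 0, camera adjusted p = 0.00033, and adjusted p = 0.754 with an estimated correlation). Lyz2, lysozyme of myeloid cells, differed by −3.11 (SE 0.95), Fn1 by −2.95 (SE 0.94) and Csf1r, the receptor for macrophage colony-stimulating factor, by −2.18 (SE 0.65). These were among the 5 of 13 members that passed adjusted over the list alone, as was Cd14, with 0 over all genes. Neutrophil markers fell (mean −1.38, 14 of 14 below 0, adjusted p = 0.00562, and adjusted p = 0.754 with an estimated correlation), with Mmp9 at −2.63 (SE 1.1) and Retnlg at −1.91. B cell (−0.82, 0.015), T cell (−0.61, 0.0397, Cd28 −1.19), hypoxia (−0.63, 0.0412, Slc2a1 −1.47) and adhesion receptor genes (−0.76, 0.0467, Fpr1 −1.94) fell as lists, with adjusted p = 0.754 with an estimated correlation as the lowest. The T cell list turned direction relative to other genes with quantile normalization (mean −0.06). Erythroid markers rose (0.96, 14 of 16 above 0, 0.0155), with Klf1, an erythroid transcription factor, at 2.59 (SE 1.19, at least 5.32-fold, not well above background in serum). None of the 7 calls held with an estimated correlation (adjusted p = 0.754 with an estimated correlation as the lowest at this time).

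Single genes at 4 h gave 0 past the threshold in limma, with 2626 at an unadjusted p under 0.05. Genes with a symbol and the smallest p values were Slc10a2 (4.52, SE 0.91, at least 5.54-fold), Sh2b2 (−2.21, SE 0.45), Rab11fip5 (−3.85, SE 0.78, at least 5.23-fold), Apoa5 (−5.89, SE 1.22, at least 24.5-fold) and Katnal2 (3.69, SE 0.79, at least 2.79-fold), all at adjusted p = 0.333. Those with a bound were not well above background in 1 group. Adjusted over the list alone, Mx1 stood at −3.17, Sftpc at −2.64 (1 of the 2 OA arrays has a value) and Scgb1a1 at −3.0, while the lung list itself was not called (mean −1.0, adjusted p = 0.124). The Sftpc value sets 1 OA array against 1 serum array, so its spread is taken wholly from other groups. Groups did not overlap for 72.7% of genes, against 66.7% by chance. With slide as a block the monocyte (−1.66, adjusted p = 0.000441) and neutrophil (−1.77, 0.000441) calls held, and the erythroid (0.224) and T cell (0.0982) calls did not. Within slide 3 the differences were −2.35 for monocyte, −1.58 for neutrophil, −1.27 for B cell, −0.87 for T cell, −1.09 for hypoxia, −1.22 for adhesion and 0.48 for erythroid genes. Leaving out OA 4 h replicate 1 ended the neutrophil (0.0574), T cell (0.0615) and erythroid (0.338) calls. Leaving out OA 4 h replicate 2 ended the B cell (0.109), T cell (0.106), hypoxia (0.376) and adhesion (0.357) calls. Arrays of other times ended the adhesion call by a small margin (at most 0.0643, without serum 24 h replicate 2), and adjusted p over the alternatives ran from 4.90e-06 to 0.999. OA 4 h replicate 2 has the high intergenic signal given above, and with that signal as a covariate the monocyte list stood at −0.90 (adjusted p = 0.00363), neutrophil at −0.97 (0.00909), B cell at 0.06, T cell at 0.09 and adhesion at −0.19.

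At 18 h neutrophil markers rose as a list after OA (mean 0.91, 13 of 14 above 0, camera adjusted p = 8.31e-09, and adjusted p = 0.754 with an estimated correlation). Cxcr2, the chemokine receptor that draws neutrophils into tissue, differed by 1.45 (SE 0.84), Hdc, which makes histamine, by 1.39 (SE 0.76) and Trem1 by 0.96. Immediate early genes (mean 0.42, 12 of 15 above 0, adjusted p = 0.00161, Atf3 1.33 with SE 0.53), inflammatory genes (0.38, 11 of 15, 0.00866, Cxcl2 2.11 with SE 0.98, Ccl2 1.13), glucocorticoid-responsive genes (0.35, 8 of 11, 0.00995) and adhesion receptor genes (0.27, 0.0412) rose as lists, each at adjusted p = 0.754 with an estimated correlation. NK markers fell (mean −0.40, 13 of 13 below 0, 0.00752, Xcl1 −0.68, Ncr1 −0.51), as did T cell markers (−0.26, 15 of 16 below 0, 0.0221, Lck −0.56 with SE 0.43). None of the 7 calls held with an estimated correlation (adjusted p = 0.754 with an estimated correlation as the lowest at this time).

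Leaving out serum 18 h replicate 1 ended the neutrophil (mean 0.27, adjusted p = 0.243), T cell (0.0504), NK (0.487), inflammatory (−0.13, 0.648), immediate early (−0.11, 0.749), glucocorticoid (0.648) and adhesion (0.959) calls at 18 h. Leaving out OA 18 h replicate 2 ended the NK (0.0569), inflammatory (0.225), immediate early (0.161) and adhesion (0.405) calls. The T cell call ended without OA 18 h replicate 3 (0.817) or serum 18 h replicate 2 (0.31). So did the NK (0.164) and adhesion (0.0635) calls without OA 18 h replicate 3 and the glucocorticoid call without OA 18 h replicate 1 (0.123). Adjusted p ranged over the alternatives from 6.80e-14 to 0.959. Exact permutation of list scores at 18 h alone gave p = 0.1 for glucocorticoid-responsive genes. For the other called lists the permutation p was 0.3 to 0.6, with 0.3 for neutrophil markers. With slide as a block the neutrophil (0.79, 6.55e-05), NK (0.00311) and immediate early (0.0422) calls held, while the glucocorticoid (0.653) and adhesion (0.225) calls did not. The intergenic covariate ended the adhesion call (0.09). Within slide 2 the differences were 1.03 for neutrophil, 0.39 for immediate early, 0.34 for inflammatory, 0.21 for glucocorticoid-responsive, 0.32 for adhesion, −0.22 for T cell and −0.26 for NK genes. No single gene passed in limma (0 genes, 253 at an unadjusted p under 0.05), and groups did not overlap for 6.92% of genes, against 20% by chance. Of genes with a symbol, Tceal6 (2.34, SE 0.59, at least 2.1-fold), Penk, the enkephalin precursor (2.45, SE 0.66, at least 1.69-fold), Armh4 (−2.47, SE 0.69, at least 1.43-fold), Il13ra1 and Akr1c12 (−2.69, at least 2.8-fold) had the smallest p values, all at adjusted p = 1. Il13ra1 was not well above background in serum, nor were those given with a bound in 1 of the groups.

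At 24 h many genes passed, 3922 higher and 4006 lower after OA (7928 genes in limma, 11870 at an unadjusted p under 0.05). This count includes unnamed transcripts, as 15012 of the 25206 genes or unnamed transcripts tested had a symbol. Monocyte markers rose as a list, with all 13 members above 0, 7 past the threshold over all genes and 12 adjusted over the list alone (mean 2.05, camera adjusted p = 7.28e-05, and adjusted p = 0.754 with an estimated correlation). Csf1r rose by 2.45 (SE 0.49, adjusted p = 0.0123), Cx3cr1, the fractalkine receptor of patrolling monocytes, by 3.27 (SE 0.69, 0.0139) and Cd300e by 3.60 (SE 0.68, 0.0103). Probes of Csf1r ran from 0.44 to 2.45. The monocyte list averaged 0.45 (SD 0.716, n = 2) in serum and 2.5 (SD 0.161, n = 3) in OA. Adgre4, a receptor of myeloid cells, rose by 3.63 (SE 0.62, at least 5.46-fold), Ear2 by 3.53 (SE 0.69) and Ear12 by 3.44 (SE 0.58), both ribonucleases of the eosinophil-associated family. Hfe, a regulator of iron uptake, rose by 3.93 (SE 0.63, at least 5.7-fold, adjusted p = 0.00668) and Bpifa6 by 3.85 (SE 1.44, at least 3.45-fold, 0.047). All bounds on rises at 24 h are for genes not well above background in serum.

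Immediate early genes rose at 24 h, 15 of 15 above 0 and 5 past the threshold both over all genes and adjusted over the list alone (mean 1.42, adjusted p = 0.00314, and adjusted p = 0.754 with an estimated correlation). Nr4a1, a nuclear receptor needed by patrolling monocytes, rose by 3.02 (SE 0.61, 0.0131), Klf4 by 2.49 (SE 0.51, 0.0136) and Atf3 by 2.47 (SE 0.53, at least 4.5-fold, 0.0139), with Jun and Zfp36 as the other members past the threshold, named after their values were seen. B cell markers rose, 13 of 13 above 0, 7 over all genes and 11 adjusted over the list alone (mean 1.29, adjusted p = 0.00079), with Ebf1 at 1.45, Cr2, a complement receptor, at 1.34 and Pax5 at 1.15, whose probes ran from −0.25 to 1.15. For this list adjusted p = 0.754 with an estimated correlation. Glucocorticoid-responsive genes (mean 1.19, 11 of 11 above 0, 4 over all genes and 5 over the list alone, adjusted p = 0.0113, and adjusted p = 0.754 with an estimated correlation) included Errfi1 at 2.07 (at least 2.33-fold, 0.016), Klf9 at 1.82 (at least 1.73-fold) and Zbtb16 at 1.19. Heat shock genes (0.94, 7 of 9 above 0, 4 and 4, 0.0393, and adjusted p = 0.754 with an estimated correlation) included the chaperones Dnajb1 at 1.5 (SE 0.37, 0.0172), Hspe1 at 1.71 and Hspa8 at 1.40. Without serum 24 h replicate 1 these chaperones stood at 0.77, 0.80 and 0.48. In the full fit the probes of Hspe1 ran from 0.19 to 1.71 and those of Hspa8 from 0.18 to 1.40.

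Targets of the fatty acid receptor PPAR and genes of fatty acid oxidation rose as a list at 24 h (mean 0.66, 14 of 18 above 0, 6 over all genes and 6 over the list alone, adjusted p = 0.0412, and adjusted p = 0.754 with an estimated correlation). Plin2, which coats lipid droplets, rose by 2.06 (SE 0.53, 0.0185), Etfdh, an electron carrier of fatty acid oxidation, by 1.87 (SE 0.43, 0.0156) and Cpt2 by 1.49, with probes from −0.37 to 1.49. Hypoxia genes (0.66, 13 of 15 above 0, 3 and 3, 0.0493, and adjusted p = 0.754 with an estimated correlation) included Hk2 at 2.02 (at least 1.67-fold), Ldha at 1.11 (probes from 0.29 to 1.11) and Adm, which was not well above background in serum and turned direction with normexp correction (−0.14). NK markers (0.93, 13 of 13 above 0, 1 over all genes and 0 over the list alone, 0.0428, and adjusted p = 0.759 with an estimated correlation) included Xcl1 at 1.54 (0.0376). T cell markers rose with 14 of 16 above 0 and 0 members past either threshold (0.60, 0.0483), and turned direction with quantile normalization and the deposited value table (means −0.00 and 0.01). None of the glucocorticoid, heat shock, PPAR, hypoxia, NK and T cell calls held with an estimated correlation (adjusted p = 0.754 with an estimated correlation as the lowest of them).

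Lung epithelial and endothelial markers fell at 24 h, with 6 of 6 measured members (of 10 fixed) below 0 and 3 past the threshold both over all genes and adjusted over the list alone (mean −2.87, camera adjusted p = 0.00334, and adjusted p = 0.242 with an estimated correlation). Sftpc, surfactant protein C of alveolar type II cells (probe at chromosome 14, 70920899 to 70921159, mm9), fell by 6.91 (SE 0.55, at least 33.6-fold, adjusted p = 8.72e-07) and was not well above background in OA. Scgb1a1, the secretory protein of airway club cells (chromosome 19, 9158197 to 9158256), fell by 5.08 (SE 0.73, 0.0032) and Epcam, an epithelial adhesion molecule, stood at −3.43 (SE 0.88, at least 4.27-fold lower, 0.0185). Other large falls were those of Rsph1, a protein of ciliary axonemes (−5.22, SE 1.14, 0.014), Ccdc149 (−5.15, SE 1.22, 0.0161) and the olfactory receptors Olfr357 (−5.15, SE 0.95, at least 10.2-fold) and Olfr1360 (−5.11, SE 1.17, at least 13.2-fold). Epcam and both olfactory receptors were not well above background in OA. Sftpc stood at 2.54 and 1.74 in the serum 24 h arrays and 0.89 in the serum 4 h array, and at −1.75 or lower wherever it was measured on another array. It was well above background on 3 of those other 27 arrays, both OA 4 h arrays and serum 1.5 h replicate 3. Scgb1a1 stood at 3.38, 2.37 and 1.61 on the same 3 serum arrays and was well above background on 23 of the other 27.

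**Figure D3:**
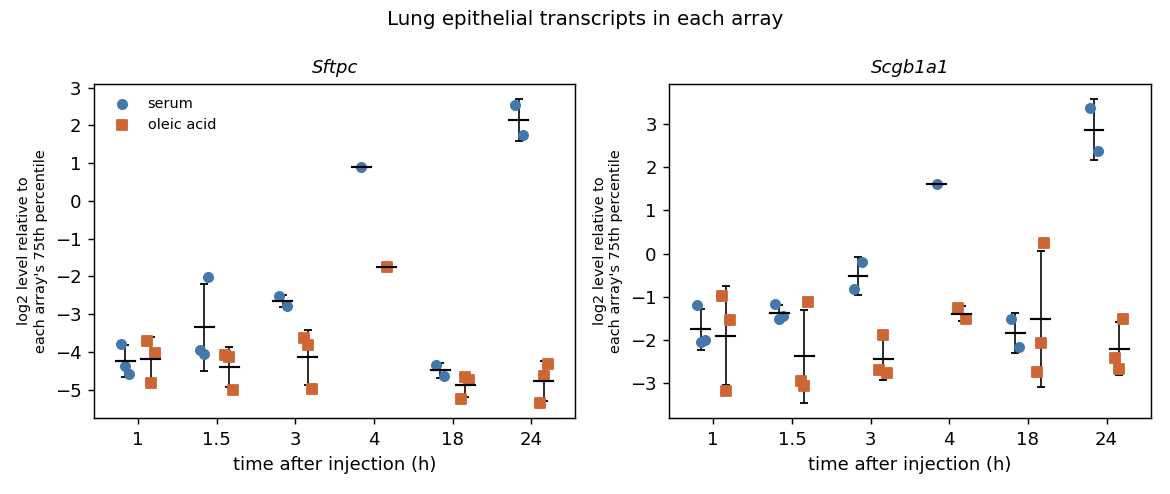
Log2 level of Sftpc and Scgb1a1, relative to the 75th percentile of the array, by hours after injection, with serum arrays as blue circles, OA arrays as orange squares, group means as black lines and SD as bars. Sftpc reached 2.54 and 1.74 in serum at 24 h and 0.89 in serum at 4 h.

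The 24 h count rested on few arrays. It was 39 without serum 24 h replicate 1, 141 without OA 24 h replicate 1, 3598 without OA 24 h replicate 2, 4409 without OA 24 h replicate 3 and 13028 without serum 24 h replicate 2. Both serum 24 h arrays lay on slide 1, so no slide held both treatments. With slide as a block 7 genes passed, including Sftpc (−6.49), Scgb1a1 (−4.47), Katnal1 (3.22), Olfr1364 (−4.26) and Olfr1256 (−3.63), the last 3 named after their values were seen. Of these, Katnal1 was not well above background in serum, nor were Sftpc and both olfactory receptors in OA. With the intergenic signal, which was higher in serum at 24 h, as a covariate, Sftpc (−5.63), Ston2 (−4.82) and Katnal1 (2.89) passed, 3 genes in all, Ston2 also being named after its values were seen. Of the 34 named genes that passed, 2 still passed with slide as a block and 1 with the covariate. All 34 kept their sign in both fits and without serum 24 h replicate 1. Without that array, which leaves a single serum array at 24 h, Sftpc stood at −6.51 and Scgb1a1 at −4.58. Many differences shrank more, as for Ldha (1.11 to 0.32), Etfdh (1.87 to 0.92), Errfi1 (2.07 to 1.16) and Ebf1 (1.45 to 0.79). Those of Cd300e, Pax5, Rsph1 and Olfr357 grew in size instead, and that of Adm hardly moved. Sftpc passed in all 45 alternatives that kept it, the stricter filter having dropped it (adjusted p from 3.54e-08 to 0.00887). With the median of always-detected probes as scaling, 1404 genes were higher and 5217 lower, so 21.2% of calls were higher against 49.5% before. That share was 83.1% with the stricter filter (4015 higher, 814 lower), 31.5% without a filter (3771 and 8210) and 5.59% with only the 2 groups of 24 h (185 and 3125). Groups did not overlap for 56.4% of genes, against 20% by chance.

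Among the lists at 24 h, slide as a block kept the monocyte (2.02, adjusted p = 8.02e-06), lung (−2.64, 0.000441), immediate early (1.08, 0.00634), B cell (0.76, 0.0116) and glucocorticoid (0.0266) calls and ended the heat shock (0.133), PPAR (0.0755), NK (0.151), T cell (0.151) and hypoxia (0.0773) calls. With the intergenic covariate the monocyte (1.19, 1.11e-06), lung (−2.55, 3.96e-08) and immediate early (0.41, 0.0326) calls held and the others did not, with T cell at −0.30, NK at −0.27 and hypoxia at −0.21. Leaving out serum 24 h replicate 1 ended the T cell (−0.14, 0.792), NK (0.346) and hypoxia (0.154) calls, and leaving out serum 24 h replicate 2 the PPAR (0.106), hypoxia (0.0605) and heat shock (0.0521) calls. OA 24 h replicate 2 ended the NK (0.0996), hypoxia (0.0997) and PPAR (0.0546) calls, OA 24 h replicate 1 the T cell call (0.0985) and OA 24 h replicate 3 the NK call (0.0536). T cell, hypoxia and NK calls also ended by a small margin without some arrays of other times (at most 0.0621, 0.0574 and 0.0503). Adjusted p over the alternatives of the 10 lists ran from 3.96e-08 to 0.905.

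Averaged over the 6 times, Sftpc was the 1 gene past the threshold in limma, with a fitted value of −2.07 (SE 0.24, adjusted p = 0.000762, 3696 genes at an unadjusted p under 0.05). That value mixes the 4 and 24 h differences with times at which Sftpc lay near background, since neither group was well above it at 1, 3 and 18 h and only 1 of 3 serum arrays at 1.5 h. Sftpc passed in each of the 43 alternatives in which it could be tested (adjusted p from 0.000162 to 0.0247). These leave out the stricter filter, which drops Sftpc, and the fits without OA 4 h replicate 1 or the serum 4 h array, since Sftpc has no value on OA 4 h replicate 2. Next came Scgb1a1 (−1.81, SE 0.31, 0.0765), Hyls1 (1.08, SE 0.20, 0.13), Maff, a stress-induced transcription factor (1.18, SE 0.24, 0.233), and Tmem253 (−0.88), with Hyls1 not well above background in serum after 1 h and Maff in serum at any time. Immediate early genes rose as a list (mean 0.56, 14 of 15 above 0, camera adjusted p = 1.85e-05, and adjusted p = 0.754 with an estimated correlation), with Zfp36, which destabilises cytokine messages, at 1.07, Atf3 at 0.95 (SE 0.22) and Nr4a1 at 0.89, and 7 members passed adjusted over the list alone against 0 over all genes. B cell (0.36, 13 of 13, 0.000439), platelet (0.46, 13 of 13, 0.00161), glucocorticoid-responsive (0.36, 0.00164), and monocyte genes (0.36, 12 of 13, 0.00433, Cd300e 1.0) also rose, each at adjusted p = 0.754 with an estimated correlation. Hypoxia (0.27, 15 of 15, 0.00616), inflammatory (0.40, 13 of 15, 0.00616, Il1b 1.07, Tnfaip3 0.84 with SE 0.23), heat shock (0.29, 8 of 9, 0.00646) and unfolded protein genes (0.27, 9 of 10, 0.0191, Atf4 0.52) rose as lists too, each at adjusted p = 0.754 with an estimated correlation. Lung markers fell (−0.81, 5 of 6 below 0, 0.00161, and adjusted p = 0.242 with an estimated correlation), with 1 member past the threshold over all genes and 3 adjusted over the list alone, Kdr at −0.59 among them. Probes of Atf4 and of Kdr disagreed.

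None of the 10 calls for the mean held with an estimated correlation (adjusted p = 0.242 with an estimated correlation for lung markers, and 0.754 as the lowest of the others). Slide as a block ended the glucocorticoid (0.0747), heat shock (0.0702) and unfolded protein (0.107) calls and the covariate those of platelet (0.07, 0.234), hypoxia (0.419) and unfolded protein genes (0.125). For these 10 lists adjusted p over the alternatives ran from 8.26e-07 to 0.754. When treatment was permuted within time, list scores, scaled to the median of always-detected probes, differed for lung markers (−0.91, permutation p = 0.00091, adjusted 0.0209), immediate early genes (0.46, 0.00321, 0.0369) and heat shock genes (0.19, 0.00597, 0.0458), 3 of 23 lists, with 7 at an unadjusted p under 0.05. The count of genes was 0 without OA 4 h replicate 1, where Sftpc could not be tested, 9 without serum 24 h replicate 2 and 5118 without the 4 h groups.

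The late minus early contrast asked whether the OA effect at 18 and 24 h differed from that at 1 to 4 h. Monocyte markers were shifted up late (1.12, 12 of 13 above 0, camera adjusted p = 5.65e-05, and adjusted p = 0.754 with an estimated correlation), with Cd14 at 2.23 and Csf1r at 1.63, both past the threshold adjusted over the list alone. Platelet markers were shifted down (−0.81, 13 of 13 below 0, adjusted p = 0.0105) and neutrophil markers up (0.76, 14 of 14, 0.0129), with adjusted p = 0.754 with an estimated correlation as the lower of these. Lung markers were shifted down (−1.09, 5 of 6, 0.0202), and glucocorticoid-responsive (0.62, 0.0312), immediate early (0.54, 0.0312), B cell (0.43, 0.0332), T cell (0.34, 16 of 16, 0.0436) and adhesion genes (0.44, 0.0499) up. None of these 9 calls held with an estimated correlation (adjusted p = 0.754 with an estimated correlation as the lowest). Adjusted over the list alone, Plin2 (1.48), Cpt1a (1.40) and Socs3 (1.36) also passed, in lists that were not called.

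No single gene passed for late minus early in limma (0 genes, 3596 at an unadjusted p under 0.05). With a symbol, the smallest p values were those of Celsr3 (2.30, SE 0.43, adjusted p = 0.135), Katnal2 (−2.70, SE 0.52, 0.135), Katnal1 (1.74, SE 0.36, 0.175, its probes from −0.98 to 1.74), Sftpc (−2.37, SE 0.50), Atp23 (−3.11, SE 0.66), Tubb6 (2.02), Olfr1364 (−2.69) and Cped1 (−1.87). All but Tubb6 were not well above background in at least 1 group, so these are fitted values. The count was 1790 without serum 24 h replicate 2 and 42 without OA 4 h replicate 1. Slide as a block kept the monocyte (1.09, 3.53e-05) and platelet (−1.08, 0.000441) calls and ended the glucocorticoid (0.107), immediate early (0.177), B cell (0.525), T cell (0.127) and adhesion (0.0882) calls. Leaving out serum 18 h replicate 2 ended the platelet call (0.636) and serum 18 h replicate 1 the neutrophil (0.126), immediate early (0.232) and glucocorticoid (0.0856) calls. OA 4 h replicate 1 decided the lung call (0.224 without it) and serum 24 h replicate 1 the B cell (0.394), T cell (0.85), glucocorticoid (0.0706) and adhesion (0.204) calls. Without serum 24 h replicate 2 the platelet (0.209), neutrophil (0.106), immediate early (0.128) and lung (0.0616) calls ended, and without OA 4 h replicate 1 the platelet (0.0933) and neutrophil (0.0572) calls. All but the monocyte call ended without still other arrays, with adjusted p of at most 0.173 (B cell, serum 3 h replicate 1). With the intergenic covariate the monocyte call held (0.000465) while B cell and T cell genes stood at −0.06 and −0.05, and adjusted p over the alternatives ran from 1.07e-13 to 0.997.

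The OA effect differed between times for 2 genes in limma's F test, with 4224 at an unadjusted p under 0.05. These were Sftpc (F = 21.8, adjusted p = 0.00296) and an unnamed long intergenic RNA probe on chromosome 1 (121054891 to 121054950, mm9, F = 15.4, adjusted p = 0.0193). Katnal1, a microtubule-severing protein, followed (F = 12.6, adjusted p = 0.0641), at 0.12 in OA and not well above background in serum at 24 h, and Katnal2 (F = 11.6). Without serum 24 h replicate 1 no gene passed, without serum 24 h replicate 2 3519 did, and without OA 4 h replicate 1 58 did. Sftpc then stood at adjusted p = 0.141 without serum 24 h replicate 1, in a range from 4.06e-05 to 0.141 over its alternatives.

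Serum groups differed between times for 11 genes (3234 at an unadjusted p under 0.05), those with a symbol being led by Sftpc (F = 40.1, adjusted p = 1.21e-05), Tardbp, an RNA-binding protein (16.8, 0.00744), Celsr3 (15.8, 0.00744), Katnal1 (14.8, 0.00861), Il13ra1 (14.1, 0.0111), Scgb1a1 (11.99, 0.0311), Lilr4b (11.4, 0.0401) and Cnga1 (11.04, 0.0476). OA groups differed for 34 genes (4504 at an unadjusted p under 0.05), those with a symbol being led by Tardbp (18.7, 0.00373), Cr2 (17.5, 0.00441), Itih4 (14.98, 0.012), Crip3 (13.5, 0.0186), Rab11fip5 (12.2), Il4i1 (11.8), Il20rb (11.7, 0.0334) and Tex45 (10.9, 0.0432). Sftpc, Celsr3, Katnal1, Il13ra1 and Cnga1 in serum and Itih4, Rab11fip5 and Tex45 in OA were not well above background at 1 or more times. Tardbp averaged 3.15, 2.14, 0.99, 2.15, 4.05 and 2.62 in serum at 1, 1.5, 3, 4, 18 and 24 h, and 3.34, 2.58, 1.80, 2.54, 4.03 and 4.11 in OA. Cr2 averaged 3.09, 2.60, 1.77, 1.69, 4.20 and 2.44 in serum and 3.61, 2.91, 1.87, 1.5, 3.90 and 3.78 in OA. Crip3 in OA lay at −0.19, −0.76, −2.21, −1.52, −0.01 and −0.01 and Il4i1 at 3.84, 3.75, 2.04, 1.83, 3.81 and 4.06. Leaving out 1 array moved the serum count between 4 (serum 18 h replicate 1) and 923 (serum 24 h replicate 2) and the OA count between 4 (OA 3 h replicate 2) and 164 (either serum 24 h array). The Tardbp call ended with the mean of its probes in both treatments (adjusted p = 0.289 in serum and 0.377 in OA, over ranges from 4.12e-07 and 3.46e-07), and with slide as a block no gene passed for OA.

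The 5 remaining lists were not called in any comparison. Dendritic cell markers stood at 0.88 at 24 h (adjusted p = 0.0659), with 3 members past the threshold over all genes and 3 adjusted over the list alone (Irf8, Itgax and Clec10a, named after their values were seen). Immature neutrophil granule genes stood at −0.92 at 4 h (0.0741) and −0.66 at 24 h (0.256). Anti-inflammatory genes stood at 0.25 at 18 h (0.0757), and at 24 h Socs3 (1.38), Il4ra (1.06), Il1rn (−1.89) and Marco (−2.26) passed adjusted over the list alone. Cell cycle genes stood at 0.19 at 1 h (0.22) and circadian clock genes at 0.16 at 1 h (0.088). Interferon-stimulated genes, called at 1.5 and 3 h, stood at 0.37 at 24 h (0.327), where Mx1 (2.31), Oas1a (1.96) and Stat2 (1.35) passed adjusted over the list alone.

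Over the 8 contrasts, 66 of 184 list tests passed, 53 up and 13 down, and 0 passed with an estimated correlation, where 9 were at an unadjusted p under 0.05. Fry passed 2 lists at 24 h, 1 for the mean and 1 for late minus early, led by lung markers at 24 h (adjusted p = 1.93e-06) and for the mean (0.00023). Slide as a block kept 43 of the 66 calls and the intergenic covariate 32. Apart from the estimated correlation, fry and the permutation of list scores, 13 calls held in every alternative run and in each fit without 1 array that could be made. They were immediate early genes at 1 h, 24 h and for the mean, platelet markers at 1.5 and 3 h, monocyte markers at 3, 4 and 24 h and for late minus early, hypoxia genes at 3 h, lung markers at 24 h and for the mean, and B cell markers for the mean. The 5 of these at 4 h, for the mean and for late minus early could not be tested without the serum 4 h array. Of the 13, fry passed those of lung markers at 24 h and for the mean and of monocyte markers at 24 h (adjusted p = 0.00426). For the mean, permutation of list scores did not pass B cell genes (permutation p = 0.0378, adjusted 0.142). At a single time exact permutation allows no p under 0.1, and immediate early genes gave p = 0.3 at 1 h and 0.2 at 24 h. Within slide 1 at 1 h they stood at −0.04, and OA 1 h replicates 2 and 3 lay on slide 5, which held no serum array. Monocyte markers at 4 h allowed only 3 arrangements. The other single-time calls among the 13 gave a permutation p of 0.1. In each called list the median and the mean of the members had the same sign.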

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

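Chosen only after the results were seen were the tests of a single array and of other splits at 24 h, all tests of the lung transcripts, both tests of the platelet genes, and the fit with the intergenic covariate as a setting.

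The OA effect differed between times for Sftpc (F = 21.8) and for a long intergenic RNA probe on chromosome 1 (F = 15.4). Between the 2 late and the 4 early times the effect differed for neutrophil (0.76), monocyte (1.12), B cell (0.43), T cell (0.34), platelet (−0.81) and lung markers (−1.09), and for immediate early (0.54), glucocorticoid-responsive (0.62) and adhesion genes (0.44). These list differences did not pass with an estimated correlation. All but that of monocyte markers also ended when some single arrays were left out. With the intergenic covariate B cell and T cell genes turned direction, at −0.06 and −0.05.

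For the 24 h count of 7928 genes, leaving out serum 24 h replicate 1, an array of high intergenic signal, gave 39 and that signal as a covariate 3, while 141 without OA 24 h replicate 1 shows that other arrays matter too. Over the genes that passed, signed by their direction in the full fit, the median difference was 1.89, with a median SE per gene of 0.559. It went to 1.23 (0.673) without that serum array, 1.51 (0.634) with slide as a block and 0.50 (0.578) with the covariate. Calls ended with the covariate through smaller differences. That signal is taken from probes that are themselves tested, and it averaged −2.90 in serum and −4.69 in OA at 24 h. Part of the fall with it may follow from how it is made. Without that serum array or with slide as a block, calls ended through smaller differences and larger errors. These genes were chosen by passing in the full fit, so smaller differences in other fits follow partly from that choice. The part due to the array cannot be told from these values. Slide stays open, because both serum arrays lay on slide 1, with 7 genes when slide was a fixed block but 5664 as a random block (within-slide correlation 0.0713), and the slide difference within 5 other groups came to 0.176 (SD 0.184) of the 24 h difference. A direct effect of OA on blood cells at 24 h stays open, and the 10 splits of 5 arrays (1 as large, highest other 2) are too few for a share under 0.05.

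The second pattern is the level of Sftpc and Scgb1a1 in all 3 arrays of the serum 4 h and 24 h groups. An effect of OA lowering a transcript that serum mice carry at every time is argued against for Sftpc. It was well above background on only 1 of the other 10 serum arrays. Both OA 4 h arrays also had Sftpc well above background, so its detection was not confined to serum mice. OA 4 h replicate 2 and that serum array, 1.5 h replicate 3, were among the 3 arrays of low correlation. Scgb1a1 was carried more widely, being well above background on 23 of the other 27 arrays. On the other 10 serum arrays it lay at −2.17 to −0.20 (SD 0.603), against 1.61 or more on these 3. As these 3 were singled out by their level, that gap cannot decide, and a lowering of Scgb1a1 by OA stays open. For 20 other lung-abundant genes (3 of them in the fixed lung list), these arrays were compared with the other 27, scaled to detected probes. The median difference was 1.27, against 0.77 for random lists of like level (percentile 99.4). Without serum 24 h replicate 1 it was 0.52 against 0.18 (percentile 99.6). Genes of the random lists were drawn independently, and these 3 arrays were singled out by Sftpc and Scgb1a1. Where lung genes vary together, both percentiles may therefore be too high. Some lung RNA in these samples would give such differences. That remains a hypothesis, as most of these genes lie near background (Sftpb well above it on 1 of the 3 and 1 of the 27 arrays, Cyp2f2 and Scgb3a1 on 2 and 5, Sftpa1 on none), and Napsa, Lamp3 and Hopx, seen on every array, differed by −0.37, −0.08 and −0.13, although their level in blood cells would hide a small share. Slide as the source is argued against by Scgb1a1. With slide as a block it went from −5.08 (SE 0.73) to −4.47 (SE 0.70), still past the threshold. Sftpc went from −6.91 (SE 0.55) to −6.49 (SE 0.61) and also passed. These are fitted values, as Sftpc was not well above background in OA at 24 h. A release of lung transcripts into blood in serum-injected mice was not tested and stays open.

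The third pattern is the platelet genes at 1.5 and 3 h. Slide as the source is argued against, since the smallest within-slide difference at these times was 1.17. Platelet carry-over that varies by chance stays open, because exact permutation of treatment over the 4 early times gave p = 0.0143 but 0.127 adjusted over the 23 lists. An effect of OA on platelets in the mononuclear layer is a candidate explanation that these arrays cannot separate from it, and the blood volume of each animal is not given in the sources used here.

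Other splits bear on 4 further counts. The numbers of splits given here include the real one. At 1 h and at 1.5 h, 10 of 10 splits gave at least the real count of 0 (highest other 0), which a count of 0 fixes in advance, and 10 splits are too few for a share under 0.05. For the mean of the 6 times 12 of 100 splits gave at least the 1 gene found, the highest other 3912, so chance is not excluded. That number of genes points to a structure of the samples, and the sides of that split differed by −0.765 in mean intergenic signal, against −0.373 for OA and serum. For late minus early 100 of 100 gave at least 0, the highest other 411, and the real count of 0 again fixes that share.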

How the results depend on the processing

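Fits without the 3 arrays of low correlation, with the intergenic covariate, and late minus early without the 4 h groups were chosen only after the data were seen. For each change below the cause was not tested, except that a filter alters the genes tested and a left-out array the arrays fitted. Of 3823 alternatives for 241 gene results, 3570 kept their side of the threshold, 180 lost the call, 72 gained it and 1 reversed. Of 7132 fits leaving out 1 array, 7020 kept it. For 24 F tests 295 of 353 and 570 of 703 kept it. For the 66 list calls 714 of 990 kept it, 261 lost it and 15 reversed, and 1792 of 1954 kept it when 1 array was left out, with 4 reversed. A change of direction was counted as reversed only where the main fit or the alternative passed. Results that passed in neither count as kept even where their direction changed. Of the 241 gene results only 34 at 24 h and Sftpc for the mean passed in the main fit. The others had no call to lose, so the share kept does not measure how well those calls held. Dim probes limit folds to bounds.

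With array weights, whose fit did not converge and depends on gene order, counts were 9069 at 1 h, 4 at 1.5 h, 7 at 3 h, 1 at 24 h, 1 for the effect differing between times, 458 for serum times and 4613 for OA times. With quantile normalization they were 4 at 4 h, 4 for late minus early, 14 for the effect differing between times, 66 for serum and 121 for OA times. With the median of detected probes they were 1, 53 and 109 for the 3 F tests. With normexp they were 2 for the mean, then 0, 5 and 22 for the F tests. Without a filter they were 11981 at 24 h, 2 for the mean and 22 for OA times, and with the stricter filter 4829 at 24 h, 0 for the effect differing between times, 18 for serum times and 40 list calls. The mean of probes gave 6 for serum times. Slide as a block gave 3 at 4 h, 7 at 24 h, 7 for the effect differing between times and 0 for OA times. Scan day as a block gave 4064 at 24 h, 2 for late minus early, 4 for the effect differing between times and 9 for OA times. The trend with robust moderation gave 2 for the mean. The deposited value table gave 5 at 4 h, 3 for the mean, 4 for late minus early, 12 for the effect differing between times, 146 for serum and 308 for OA times. Only the 2 groups of a time gave 1 at 4 h and 3310 at 24 h. The mean without the 4 h groups gave 5118. Without the 3 arrays of low correlation counts were 54 at 24 h, 1 for the effect differing between times and 16 for OA times. The intergenic covariate gave 3 at 24 h, 1 for late minus early, 46 for serum and 66 for OA times. Estimated correlation left 0 list calls. At 24 h, 34 of the 39 genes found without serum 24 h replicate 1, 7 of 7 with slide as a block, 3 of 3 with the covariate and 48 of 54 without the low-correlation arrays were among the 7928.

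With the replicate block, 2 genes passed for the mean, 10 for OA times and 5713 at 24 h. The numbers share no more than a name, as 12 same-numbered pairs correlated from −0.536 to 0.418, with 4 above 0.1 and 5 below −0.1.

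Leaving out each array in turn gave 0 to 0 genes at 1 h, 0 to 1 at 1.5 h, 0 to 3 at 3 h, 0 to 1 at 4 h, 0 to 5 at 18 h, 39 to 13028 at 24 h, 0 to 9 for the mean, 0 to 1790 for late minus early, 0 to 3519 for the effect differing between times, 4 to 923 for serum times, 4 to 164 for OA times, and 39 to 72 list calls. The single serum 4 h array could not be left out at 4 h, for the mean, late minus early, the effect differing between times or serum times. The lowest and highest came without OA 4 h replicate 1 or 2 (1.5 h), serum 3 h replicate 1, OA 4 h replicate 1, serum 18 h replicate 2, serum 24 h replicates 1 and 2, serum 18 h replicate 1 (4, serum times), OA 3 h replicate 2 (4, OA times), and serum 4 h replicate 1 (39 list calls, over only the 5 contrasts then left, which held 40 of the 66, with 53 as the next lowest).

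Reversed were Adm at 24 h with normexp (−0.14), and with the intergenic covariate platelet (−0.31) and hypoxia (−0.045) genes at 1 h, B cell (0.062), T cell (0.094) and adhesion (−0.19) genes at 4 h, T cell (−0.30), NK (−0.27) and hypoxia (−0.21) genes at 24 h, and B cell (−0.062) and T cell (−0.054) genes for late minus early. List directions are relative to other genes. T cell genes reversed at 4 h with quantile normalization (−0.063) and the value table (−0.072), at 24 h with quantile normalization (−0.0024), the value table (0.012), without the 3 low-correlation arrays (−0.14) and without serum 24 h replicate 1 (−0.14), and at 18 h without OA 18 h replicate 3 (0.013). Without serum 18 h replicate 1, inflammatory (−0.13) and immediate early (−0.11) genes reversed at 18 h. Over all arrays left out in turn, these values ran from −0.14 to 1.35 for T cell genes at 24 h, −0.49 to 0.013 for T cell, −0.13 to 0.89 for inflammatory and −0.11 to 0.95 for immediate early genes at 18 h.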

Other observations

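Tests of single clock genes over time and of members adjusted over the list alone outside called lists were singled out after the values were seen.

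Among dendritic cell markers, whose list was not called, Irf8, a transcription factor of these cells, Itgax and Clec10a were higher after OA at 24 h adjusted over the list alone. The unfolded protein response list was not called at 24 h either, yet Xbp1 (1.65), Herpud1 (1.5) and Hspa5 (1.46) were higher adjusted over the list alone. The neutrophil chemokine Cxcl1, not well above background in OA, was at least 2.18-fold lower at 24 h, opposite to Tnfaip3 (1.71) of the same inflammatory list. As with other calls at 24 h, these rest on the serum 24 h arrays.

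Blood was drawn at 6 times after injection, so clock genes were set against time. Of 9 measured clock genes, Nr1d1, which codes for a repressor of the clock, differed between times in serum (F = 6.76) and in OA (F = 6.02), 1 of 9 in each. Adjusted over the list alone these gave 0.00531 and 0.0107, and over all genes 0.183 and 0.0976. Nr1d1 averaged −2.0 and −1.63 in serum and −2.04 and −1.72 in OA at 1.5 and 3 h, and was not well above background in serum at 1, 18 and 24 h nor in OA at 4 and 18 h, so its F values rest partly on levels near background. The hour of injection is not given in the sources used here.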
